A study of Homo sapiens with 7 samples.

How the data were processed

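RNA-seq gene counts of 7 libraries of HCT116 p53-/- cells were analysed, with 1 library in each of 7 groups. HCT116 is an established human colon carcinoma line, and the p53-/- derivative lacks functional p53, a transcription factor. Per the labels, the cells were infected with wild-type p53, p53-M133T, p53-R273H or a control that the series design calls vector and the treatment protocol calls vehicle (vector here), and the vector, p53-M133T and p53-R273H cells were sequenced with and without arsenic trioxide (ATO) at 1 µg/ml for 24 h. The authors deposited 1 table of whole-number counts per gene, not normalized, with 1 column per library, and all columns were used. Per the labels' protocols, libraries were made with a TruSeq kit and read in pairs of 150 bp on the HiSeq Xten platform. Per the submitters' processing notes, FastQC, cutadapt, STAR and the hg38 genome build were used, without versions. The counting program, gene annotation and strand setting are not given in the sources used here.

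The table held 19699 genes under Ensembl identifiers. All 19699 identifiers were found in GENCODE release 29 on hg38 as protein-coding genes, which gave the coordinates, exon lengths and GC contents used here. In the deposited table, 28 symbols had been turned into date numbers by a spreadsheet and 18 genes shared a symbol with another gene. These took their GENCODE symbols by identifier, and the other genes kept their deposited symbols. No gene lacked a name. Exons overlapped those of another gene on the same strand for 2050 genes and on the opposite strand for 3508 genes. Because the counting rule and strand setting are not known, values of genes that share exons, and of near-identical copies, are uncertain.

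Total counts were 25062996 for wild-type p53, 34474017 for vector, 38577709 for vector with ATO, 39297534 for p53-M133T, 39173297 for p53-M133T with ATO, 34358002 for p53-R273H and 35220636 for p53-R273H with ATO. A count of 3, the upper limit that a count of 0 allows, corresponded to between 0.076 and 0.116 CPM. CPM values were scaled with the trimmed mean of M-values (TMM) of edgeR 4.0.16 in R 4.3.3, with factors between 0.967 and 1.031. The description field gives the wild-type library a name with another numeric prefix (190612) than the other 6 libraries (190312), so a batch and the wild-type genotype cannot be told apart.

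Each group had 1 library, so 6 comparisons of 2 libraries were described without p-values: ATO against no ATO in each of the 3 lines, and each of the 3 p53 forms against vector without ATO. For these, log2 ratios of TMM-scaled CPM with a pseudocount of 1 were computed over 12661 genes with at least 1 CPM in at least 1 library, with a size rule of 2-fold. Printed folds are ratios of scaled counts without the pseudocount, with 95% Clopper-Pearson intervals of the split of counts between both libraries. A fold against a count of 0 was computed against 3 counts and is a bound. Intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules, and these comparisons have no replicate check.

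The 4 tests used edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, after edgeR's filter on low counts, on the 6 vector, p53-M133T and p53-R273H libraries. The first test modelled the ATO effect common to the lines, with the cell line as a block, over 13572 genes and 2 residual degrees of freedom. The other 3 tests asked, for each line in turn, whether its ATO effect differed from the mean ATO effect of the other 2 lines, over 13974 genes and 1 residual degree of freedom, which comes from the difference between those 2 effects. That spread was shared across genes, with prior degrees of freedom of 157.5 for p53-M133T, 32.24 for p53-R273H, 6.96 for vector and 5.95 for the common test, so a gene's own spread counts for less than the shared one, and least in the test of p53-M133T. The DESeq2 Wald test gave no adjusted p for 7044 genes in the test of p53-M133T and 527 in the common test, and these count as not called. The lines stand in for replicates in all 4 tests, so the p-values measure the spread between lines and assume that it also describes the spread between cultures, which was not measured. The 3 tests of single lines use the same 6 libraries and are not independent of each other. Libraries of a shared line made the pairs. The correlations of the deviations of the 2 libraries of a line from their treatment means were -0.00917 for vector, 0.0676 for p53-M133T and 0.11 for p53-R273H.

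Before the data were examined, 30 gene lists were fixed: p53 core targets, p53 targets shared with other stress pathways, p53 apoptosis targets, p53 DNA repair targets, G2/M cell cycle, G1/S and DNA replication, metallothioneins and zinc export, NRF2 antioxidant response, heat shock response, ATF4 integrated stress response, ER unfolded protein response, proteasome subunits, cholesterol synthesis, hypoxia and glycolysis, immediate early genes, NF-kB and inflammatory genes, interferon-stimulated genes, mesenchymal genes, intestinal epithelial genes, WNT targets, autophagy and lysosome, ribosome biogenesis, ribosomal proteins, nuclear-encoded respiratory chain, mitochondrially encoded transcripts, replication-dependent histones, fibroblast markers, leukocyte markers, erythroid and endothelial markers, and PML body genes. Some genes stand in more than 1 list. Every listed symbol was matched to a gene, and older and newer symbols of the same gene were merged, which left 16 genes of 17 symbols for immediate early genes, 13 of 14 for mesenchymal genes, 22 of 24 for the respiratory chain and 11 of 20 for histones. In the comparisons of 2 libraries, a list's median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart where its percentile was under 2.5 or over 97.5, and the percentile describes these libraries and is not a p-value. In the 4 tests, lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation as an alternative. The preset value takes the members of a list as almost independent. For members that move together, such as the mitochondrially encoded transcripts, its p-values are too small. The estimated correlation rests on the 2 or 1 residual degrees of freedom of a test. With so few, hardly any list can be called, so a call lost with it does not decide. Counts of list members past the threshold were also made with p-values adjusted over the list alone.

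The genes named in the text were chosen by a rule fixed before the data were examined. The rule took 10 p53 targets in every library, up to 4 members with the largest change from each list that stood apart or was called, and the 8 highest and 8 lowest genes of each comparison at or above 10 CPM. In the 4 tests these highest and lowest genes were taken among those past the threshold. Results of some genes that the rule would name are not reported here. Genes named outside this rule are marked as chosen after their values were seen. Whether the genes at least 2-fold higher or lower in wild-type p53 than in vector cells moved with ATO was examined with 2 lists made from that comparison and with correlations across genes.

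Alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter or a mean of at least 10 CPM, no block, leaving out each line, pseudocounts of 0.1 and 5, scaling by column totals, a floor of 10 CPM or none, size rules of 1.5-fold and 3-fold, means in place of medians, random lists not matched on expression, and Spearman in place of Pearson correlations. A correction for exon length and GC content (natural splines with 5 degrees of freedom), the removal of genes that share exons, and tests among the 3 treated libraries alone were added after the data were examined.

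The tests were tried on simulated counts drawn from the real means and library sizes. Each unchanged gene had the same mean in all 6 libraries, and all genes had the test's common dispersion. Differences between lines, spread particular to a gene and trends with length or GC content were left out. The figures therefore do not measure false calls in the real data. For the common ATO test, 98% of genes changed 2-fold and 87% of those changed 1.5-fold were recovered, and 11 unchanged genes were called among 13426. For the test of p53-M133T, 81.8% and 65.3% were recovered with 7 unchanged genes called among 13652. For p53-R273H, 73% and 23.7% were recovered with 2 unchanged genes called among 13651, and for vector, 52.5% and 11.2% with 6 among 13658. In simulated pairs of libraries over 12661 genes, 95.3% of the intervals held the true fold and 96% of genes changed 4-fold passed the size rule. These pairs were drawn with counting error alone, which the intervals assume, so their coverage was set in advance. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.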

Results

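RNA-seq gene counts were deposited for 7 libraries of HCT116 p53-/- cells, a human colon carcinoma line without functional p53. The 7 groups held 1 library each: wild-type p53, vector, vector with arsenic trioxide (ATO), p53-M133T, p53-M133T with ATO, p53-R273H and p53-R273H with ATO. There were no replicates of any group. M133T and R273H are substitutions in the DNA-binding domain of p53, a transcription factor, and ATO is an arsenic compound used to treat acute promyelocytic leukemia. Total counts per library ranged from 25062996 for wild-type p53 to 39297534 for p53-M133T. The 10 most abundant genes took between 5.69% and 6.57% of the counts, and mitochondrially encoded transcripts took between 1.41% and 4.59%. Values are CPM after TMM scaling, and folds between 2 libraries carry a 95% Clopper-Pearson counting interval, which covers counting error alone.

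The p53 targets were counted in every library. CDKN1A (ENSG00000124762, hg38 chromosome 6, 36676460 to 36687339, plus strand), a p53 target that encodes the cell cycle inhibitor p21, stood at 60.9 CPM in vector cells and 196 CPM in wild-type p53 cells. It stood at 85.0 CPM in p53-M133T cells and 357 CPM in p53-M133T cells with ATO, against 61.5 and 74.6 CPM in p53-R273H cells without and with ATO. MDM2 (ENSG00000135679, chromosome 12, 68808176 to 68850686, plus strand), a p53 target whose product degrades p53, stood at 150 CPM in vector cells, 243 CPM in wild-type p53 cells and 550 CPM in p53-M133T cells with ATO.

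**Figure D1:**
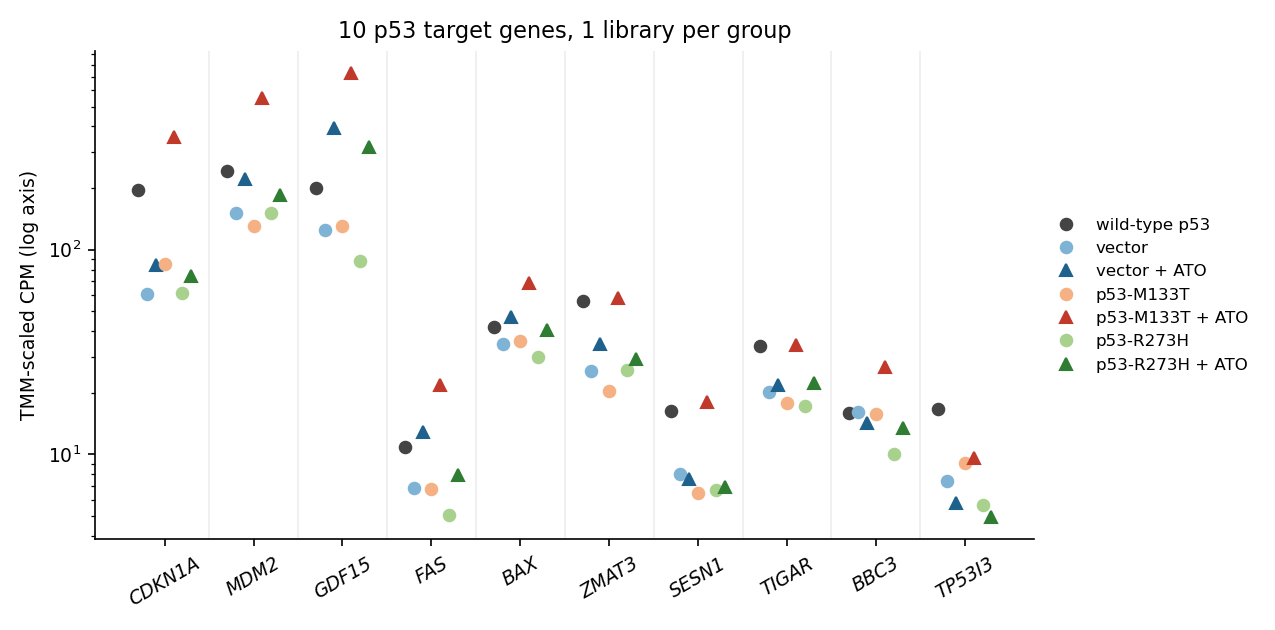
TMM-scaled CPM, on a log axis, of 10 p53 targets in the 7 libraries, 1 point per library. CDKN1A stood at 357 CPM in p53-M133T cells with ATO and at 74.6 CPM in p53-R273H cells with ATO.

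The comparison of wild-type p53 with vector cells asked what wild-type p53 did to transcript levels in these cells without ATO. CDKN1A was higher by 3.22-fold (3.06 to 3.39) and MDM2 by 1.62-fold (1.56 to 1.68). Among other p53 targets, TP53INP1, a regulator of stress-induced cell death, was higher by 3.96-fold (3.59 to 4.37), ZMAT3 by 2.2-fold (2.02 to 2.39) and SESN1 by 2.04-fold (1.75 to 2.38). The apoptosis gene BBC3 had a ratio of 0.997 (0.876 to 1.13). The median log2 ratio of 75 p53 core targets was 0.30, above all of 10000 matched random lists (percentile 100). Of these targets, 61 had a log2 ratio above 0, with 7 at least 2-fold higher and 1 at least 2-fold lower. The median of the p53 apoptosis targets was 0.34 (percentile 99.77). The p53 DNA repair targets (0.155; percentile 80.34) and the p53 targets shared with other stress pathways (0.017; percentile 58.19; 11 of 19 above 0) did not stand apart.

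Some gene groups outside the p53 lists had medians farther from 0 than the p53 lists, and others had medians closer to it. Interferon-stimulated genes, the antiviral response, had a median log2 ratio of 2.69, with 19 of 20 members at least 2-fold higher. IFI27 was higher by 181-fold (118 to 293), IFI6 by 61.0-fold (51.9 to 72.1) and IFIT1 by 28.5-fold (24.3 to 33.6). Hypoxia and glycolysis genes had a median of 1.49, with 15 of 22 members at least 2-fold higher. ANKRD37 was higher by 15.8-fold (12.9 to 19.5), the glucose transporter gene SLC2A3 by 9.54-fold (8.46 to 10.8) and NDRG1 by 8.23-fold (7.96 to 8.51). Cholesterol synthesis genes had a median of 0.83, and INSIG1, a sterol sensor, was higher by 3.87-fold (3.73 to 4.02). Immediate early genes (median 0.53), NF-kB and inflammatory genes (0.52) and replication-dependent histones (0.56) also had medians above 0. G1/S and DNA replication genes had a median of -1.11, with 27 of 34 members at least 2-fold lower. G2/M cell cycle genes had a median of -0.735 (percentile 0), with 3 of 35 members at least 2-fold lower and 0 above 0. The DNA polymerase alpha subunit gene POLA2 was lower, at a ratio of 0.216 (0.185 to 0.25), as was the replicative helicase gene MCM2, at 0.383 (0.368 to 0.399). ATF4 integrated stress response genes had a median of -0.99, and CHAC1, a glutathione-degrading enzyme, had a ratio of 0.118 (0.098 to 0.142). Asparagine synthetase, ASNS, had a ratio of 0.253 (0.242 to 0.264). Mitochondrially encoded transcripts had a median of -1.34, with 11 of 13 at least 2-fold lower, and ribosome biogenesis genes had one of -0.40. The heat shock response (-0.27; percentile 2.34) and proteasome subunits (-0.19; percentile 2.21) stood below, and autophagy (0.22; percentile 98.91) and ribosomal proteins (0.15; percentile 99.98) above their random lists.

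In all, 364 of 12661 genes were at least 2-fold higher in wild-type p53 than in vector cells and 248 were at least 2-fold lower. Of the 10 leukocyte markers listed, 3 were at or above the floor, with a median of 2.43, and 2 were at least 2-fold higher. The other members did not reach the floor in any library. CD68 had a ratio of 6.75 (5.64 to 8.13), and LYZ one of 22.6 (11.6 to 50.5). The myeloid enzyme gene MPO, which is not in that list, had 868 counts in wild-type p53 cells and 31 in vector cells. These values lay in the same library as the interferon and hypoxia values. The wild-type library carries another name prefix than the other 6, so batch and genotype cannot be told apart in any of these differences. BIVM-ERCC5 was at least 224-fold lower and CXCR5 at least 130-fold lower, with 0 counts in wild-type p53 cells, and genes that share exons such as BIVM-ERCC5 are uncertain because the counting rule is not given.

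The comparisons of p53-M133T and p53-R273H with vector cells asked what each variant did without ATO. In p53-M133T cells, CDKN1A was higher by 1.4-fold (1.32 to 1.47) and MDM2 had a ratio of 0.871 (0.838 to 0.905). In p53-R273H cells, CDKN1A had a ratio of 1.01 (0.95 to 1.07) and MDM2 one of 1 (0.962 to 1.04). The p53 core targets had a median log2 ratio of 0.01 (percentile 40.56) in p53-M133T cells and of -0.06 (percentile 0) in p53-R273H cells, where 27 of 75 targets lay above 0. RPS27L had a ratio of 0.508 (0.458 to 0.564), TP53INP1 one of 0.622 (0.541 to 0.715) and BBC3 one of 0.623 (0.544 to 0.713) in p53-R273H cells.

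Few genes passed the size rule in either variant. In p53-M133T cells 12 genes were at least 2-fold higher and 14 at least 2-fold lower than in vector cells, and in p53-R273H cells 9 and 13. With a pseudocount of 5 these counts were 2 and 0 in p53-M133T cells and 1 and 0 in p53-R273H cells. In p53-M133T cells, the extracellular matrix gene VCAN had a ratio of 0.421 (0.369 to 0.479) and ANXA10 was higher by 1.76-fold (1.54 to 2.01). The median log2 ratio in p53-M133T cells was 0.31 for mitochondrially encoded transcripts, 0.16 for ribosomal proteins, 0.19 for the heat shock response, 0.13 for proteasome subunits, 0.13 for the nuclear-encoded respiratory chain, 0.14 for ribosome biogenesis and -0.35 for replication-dependent histones. In p53-R273H cells it was 0.15 for the heat shock response, with HSPA1A higher by 1.8-fold (1.44 to 2.25). It was -0.26 for p53 targets shared with other stress pathways, -0.20 for ATF4 genes, -0.51 for replication-dependent histones, -0.145 for ribosomal proteins (0 of 34 above 0) and -0.09 for the respiratory chain. It was -0.17 for p53 apoptosis targets, -0.10 for p53 DNA repair targets (percentile 1.29), -0.18 for metallothioneins, -0.055 for NRF2 genes and -0.03 for proteasome subunits, all below percentile 2.5. Log2 ratios followed exon length across genes, with a Spearman correlation of -0.431 in p53-M133T cells and 0.299 in p53-R273H cells, where genes are not independent replicates. The erythroid and endothelial markers had medians of -1.84 in p53-M133T cells and -1.96 in p53-R273H cells, and among them the globin gene HBB had 156 counts in vector cells, 0 in p53-M133T cells and 2 in p53-R273H cells.

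The test of ATO across the vector, p53-M133T and p53-R273H lines asked which genes ATO changed in common. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3021 of 13572 genes rose and 2838 fell, of which 139 rose and 310 fell at least 2-fold. HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214, plus strand), which encodes the heme-degrading enzyme heme oxygenase 1, rose by a log2 of 6.25 (SE 0.06; 75.9-fold; adjusted p = 1.9e-09). It stood at 25.045, 30.6 and 22.6 CPM in vector, p53-M133T and p53-R273H cells without ATO and at 2011, 2229 and 1711 CPM with ATO. MT2A (ENSG00000125148, chromosome 16, 56608199 to 56609497, plus strand), a metal-binding metallothionein, rose 9.28-fold (adjusted p = 7.1e-08). All 5 of the metallothionein and zinc export genes tested rose, also when adjusted over the list alone, among them MT1X (8.08-fold) and the zinc exporter gene SLC30A1 (2.49-fold). Of the NRF2 antioxidant response genes 22 of 27 rose and 1 fell (22 and 1 adjusted over the list alone). GCLM, a subunit of the enzyme that begins glutathione synthesis, rose 5.54-fold, and the cystine transporter gene SLC7A11 rose 4.16-fold.

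Stress response groups rose in part. Of the ATF4 integrated stress response genes 21 of 23 rose and 0 fell (22 and 0 adjusted over the list alone; edgeR gave 22 and 0 at an unadjusted p under 0.05 and DESeq2 21 and 0), among them NUPR1 (4.97-fold) and TRIB3 (2.42-fold). Of 19 p53 targets shared with other stress pathways 11 rose and 1 fell (12 and 2 adjusted over the list alone), and GDF15, a stress-induced cytokine gene, rose 3.96-fold. Of 16 autophagy and lysosome genes 11 rose and 1 fell (11 and 1 adjusted over the list alone), with the selective autophagy receptor gene SQSTM1 up 2.34-fold and MAP1LC3B up 2.36-fold. Of 18 heat shock genes 9 rose and 1 fell (9 and 1 adjusted over the list alone), with the chaperone gene HSPA8 up 1.7-fold. Of 31 proteasome subunit genes 16 rose and 0 fell (16 and 0 adjusted over the list alone; edgeR gave 19 and 0 at an unadjusted p under 0.05 and DESeq2 16 and 0), with PSMD14 up 1.34-fold. The proteasome count was 4 without the vector pair, 26 without the p53-M133T pair and 10 without the p53-R273H pair, and the list's median log2 ratio was 0.06 (percentile 48.28) in p53-M133T cells, 0.26 in p53-R273H cells and 0.24 in vector cells.

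Other groups fell in part. Of 23 cholesterol synthesis genes 1 rose and 15 fell (1 and 15 adjusted over the list alone). The lanosterol synthase gene LSS fell to 0.417-fold and the sterol sensor gene INSIG1 to 0.602-fold. Of 34 G1/S and DNA replication genes 1 rose and 17 fell (1 and 18 adjusted over the list alone), with the helicase gene MCM7 at 0.393-fold. Of 13 mitochondrially encoded transcripts 0 rose and 10 fell (0 and 12 adjusted over the list alone; edgeR gave 0 and 12 at an unadjusted p under 0.05 and DESeq2 0 and 2; without genes that share exons 6 of 8 fell), with MT-ND2 at 0.546-fold. The lines differed in these transcripts: the list's median log2 ratio was -0.91 in p53-M133T cells, -0.62 in vector cells and 0.01 in p53-R273H cells, where 7 of 13 lay above 0. Without the vector pair 2 mitochondrially encoded transcripts, 7 G1/S genes and 7 cholesterol synthesis genes fell.

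The camera test with a preset correlation called 10 lists: metallothioneins (adjusted p = 4.27e-54), NRF2 (6.77e-52), ATF4 (2.08e-17), autophagy (1.21e-07), cholesterol synthesis and p53 targets shared with stress pathways (both 4.81e-06), heat shock (2.83e-04), G1/S (0.00132), proteasome (0.00387) and mitochondrially encoded transcripts (0.00757). The estimated correlation rests on 2 residual degrees of freedom and called 0 lists, so it does not decide whether these 10 calls hold. With it camera's adjusted p was 0.115 for metallothioneins, 0.164 for NRF2, 0.262 for autophagy and 0.478 for cholesterol synthesis. It was 0.576 for ATF4, 0.808 for the stress-shared targets and 0.812 for the other 4 lists.

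The p53 core targets were not called across the lines (camera adjusted p = 0.145), although 27 of 76 rose and 13 fell (28 and 14 adjusted over the list alone; 17 and 8 by DESeq2; 30 and 8 with the length and GC correction). CDKN1A rose 1.92-fold (adjusted p = 0.037) and MDM2 1.95-fold (0.03) by edgeR's quasi-likelihood test, and their ratios differed between lines as given for each line. BBC3 (log2 0.34), SESN1 (0.50) and TP53I3 (-0.15) did not pass. Members past the threshold in other lists that camera did not call, rising and falling, were 6 and 3 of 14 p53 apoptosis targets, 2 and 0 of 7 p53 DNA repair targets (edgeR 3 and 1 at an unadjusted p under 0.05, DESeq2 2 and 0), 9 and 2 of 35 G2/M genes, 9 and 7 of 17 ER unfolded protein response genes and 5 and 9 of 22 hypoxia genes. They were 4 and 4 of 16 immediate early genes, 2 and 1 of 11 NF-kB genes, 1 and 5 of 18 interferon-stimulated genes, 2 and 4 of 10 mesenchymal genes, 3 and 2 of 9 intestinal epithelial genes, 1 and 2 of 8 WNT targets, and 6 and 2 of 20 ribosome biogenesis genes. They were 5 and 0 of 34 ribosomal protein genes, 0 and 7 of 22 nuclear-encoded respiratory chain genes, 0 and 5 of 9 histones, 2 and 2 of 6 PML body genes, 1 and 1 of 3 fibroblast markers, 1 and 0 of 3 leukocyte markers and 0 and 1 of 4 erythroid and endothelial markers. Where 1 direction had 0 members, it also had 0 at an unadjusted p under 0.05 by edgeR and 0 by DESeq2, apart from the DNA repair targets given above. Adjusted over the list alone, rising and falling, the counts were 8 and 2 for G2/M genes, 3 and 4 for mesenchymal genes, 1 and 0 for ribosomal proteins, 0 and 6 for the respiratory chain and 3 and 2 for PML body genes, and equal to those given for the other lists that camera did not call. Leaving out a line moved several of these counts. Without the vector pair 5 core targets, 4 ER unfolded protein response genes, 1 respiratory chain gene and 2 histones fell, and 1 G2/M gene, 2 hypoxia genes, 1 ribosome biogenesis gene and 0 ribosomal protein genes rose. Without the p53-M133T pair 19 G2/M genes and 20 ribosomal protein genes rose, and without the p53-R273H pair 1 ribosomal protein gene rose. Ribosomal protein genes that rose numbered 17 with the length and GC correction, 8 with no filter, 2 with a mean of at least 10 CPM and 0 with no replicate block. Counts of 4 or fewer moved in other lists too. Median, mean and camera differed in sign for the mesenchymal, intestinal epithelial and leukocyte lists.

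The 3 lines served as replicates here, with 2 residual degrees of freedom. Without the vector pair, 1511 genes rose and 1403 fell. The log2 fold changes of this test correlated across genes with GC content at a Spearman coefficient of -0.371 and with exon length at 0.169. With the length and GC correction 3347 genes rose and 2427 fell. Of the 3021 and 2838 calls without it, 2406 and 1953 stayed. A trend with GC content that the 3 pairs share counts as an ATO effect in this test.

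**Figure D2:**
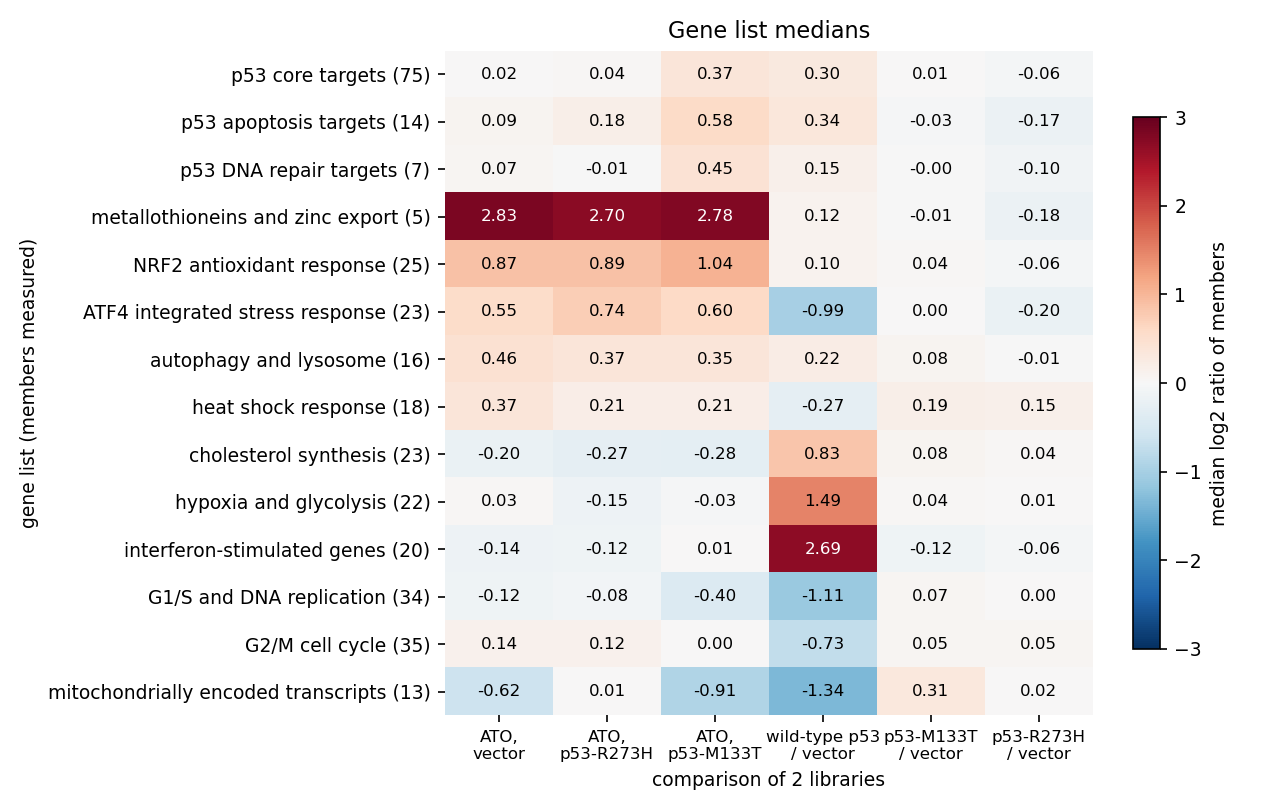
Heat map of the median log2 ratio of 14 gene lists in the 6 comparisons of 2 libraries. The p53 core targets had a median of 0.37 with ATO in p53-M133T cells, 0.04 in p53-R273H cells and 0.02 in vector cells.

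The comparison of p53-M133T cells with and without ATO asked whether ATO raised p53 target transcripts in cells with this variant. CDKN1A was higher by 4.2-fold (4.04 to 4.36), MDM2 by 4.2-fold (4.07 to 4.33), GDF15 by 5.58-fold (5.42 to 5.75), the death receptor gene FAS by 3.23-fold (2.81 to 3.73), SESN1 by 2.76-fold (2.39 to 3.2) and BAX, a pore-forming apoptosis gene, by 1.91-fold (1.79 to 2.04). TP53I3 had a ratio of 1.06 (0.913 to 1.23). Of 75 p53 core targets 60 had a log2 ratio above 0 and 13 were at least 2-fold higher, with a median of 0.37 (percentile 100). The medians were 0.58 for p53 apoptosis targets, 0.445 for p53 DNA repair targets, 0.59 for the stress-shared p53 targets and -0.22 for the respiratory chain, and these lists stood apart. So did lists that changed in all 3 lines: in p53-M133T, p53-R273H and vector cells, in that order, the medians were 1.04, 0.89 and 0.87 for NRF2, 0.60, 0.74 and 0.55 for ATF4, 0.355, 0.37 and 0.46 for autophagy, 0.21, 0.21 and 0.37 for heat shock, -0.285, -0.27 and -0.20 for cholesterol synthesis and -0.40, -0.08 and -0.12 for G1/S genes. In all, 171 genes were at least 2-fold higher and 123 at least 2-fold lower with ATO, and 142 and 148 when scaled by column totals.

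Whether the ATO effect in p53-M133T cells differed from that in the vector and p53-R273H lines was tested across genes. The ATO effect was more positive in p53-M133T cells for 816 of 13974 genes and more negative for 340 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These p-values rest on 1 residual degree of freedom and 157.5 prior degrees of freedom, so almost wholly on dispersion shared across genes. Of 78 p53 core targets, 33 rose relative to the other lines and 0 fell (43 and 0 adjusted over the list alone; edgeR gave 48 and 0 at an unadjusted p under 0.05 and DESeq2 8 and 0). The difference in log2 ratio was 1.70 for CDKN1A (SE 0.09; adjusted p = 5.4e-37), 1.64 for MDM2 (SE 0.09; 1.1e-35), 1.49 for SESN1 (SE 0.21; 1.1e-08) and 1.2 for ZMAT3 (SE 0.12; 8.4e-15). It was 0.37 for TP53I3 (adjusted p = 0.38), which did not pass. Of 15 p53 apoptosis targets 8 rose and 0 fell (9 and 0 adjusted over the list alone; edgeR 9 and 0 at an unadjusted p under 0.05, DESeq2 2 and 0), among them FAS (0.91) and BBC3 (0.67). Of 7 p53 DNA repair targets 5 rose and 0 fell (6 and 0 adjusted over the list alone; edgeR 6 and 0 at an unadjusted p under 0.05, DESeq2 2 and 0), among them DDB2 (0.88), which recognises ultraviolet damage, and the ribonucleotide reductase subunit gene RRM2B (0.80). XPC, at 0.29, did not pass. Of 19 p53 targets shared with stress pathways 8 rose and 0 fell (9 and 0 adjusted over the list alone; edgeR 9 and 1 at an unadjusted p under 0.05, DESeq2 3 and 0), GDF15 by 0.74. Camera called all 4 p53 lists with the preset correlation: adjusted p = 4.67e-26 for core targets, 4.25e-09 for apoptosis, 1.95e-08 for DNA repair and 1.6e-06 for stress-shared targets. None of the 4 was called with an estimated correlation, which rests on 1 residual degree of freedom and does not decide. Camera's adjusted p was then 0.776 for the first 3 and 0.782 for the stress-shared targets.

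Some members of cell cycle, mitochondrial and other groups fell in p53-M133T cells relative to the other lines, by edgeR and in most groups not by DESeq2. DESeq2 gave no adjusted p for 7044 of the 13974 genes of this test, so those genes count as not called in each DESeq2 count given for it. Of 34 G1/S and DNA replication genes 0 rose and 13 fell (0 and 27 adjusted over the list alone; edgeR 0 and 28 at an unadjusted p under 0.05, DESeq2 0 and 0), with the replication helicase gene GINS2 at a log2 difference of -0.58 (adjusted p = 4.1e-06) and POLA2 at -0.51. Of 35 G2/M genes 2 rose and 6 fell (2 and 10 adjusted over the list alone; edgeR 2 and 14 at an unadjusted p under 0.05, DESeq2 1 and 0), with the mitotic kinase gene AURKB at -0.40. In p53-M133T cells the G2/M median log2 ratio with ATO was 0.001, with 18 of 35 above 0. The risers MKI67 (0.43) and CENPF reversed to -0.04 and -0.007 when the 3 treated libraries alone were compared. All 13 mitochondrially encoded transcripts fell (13 adjusted over the list alone; DESeq2 called 0; without genes that share exons 8 of 8 fell), with MT-CO2 at -0.79. Their share of counts was 4.59% in p53-M133T cells, the highest of the 7 libraries, and 2.35% with ATO, against 3.69% and 2.3% in vector cells. Proteasome subunits (0 rose and 4 fell of 31; 0 and 5 adjusted over the list alone; edgeR 0 and 9 at an unadjusted p under 0.05, DESeq2 0 and 0), ribosomal proteins (0 and 4 of 34; 0 and 4 alone; 0 and 9; 0 and 1) and nuclear-encoded respiratory chain genes (0 and 2 of 22; 0 and 6 alone; 0 and 9; 0 and 0) fell in part. Camera's adjusted p with the preset correlation was 1.29e-16 for G1/S, 2.87e-16 for mitochondrial transcripts, 1.6e-06 for ribosomal proteins, 1.84e-06 for the proteasome, 3.89e-06 for G2/M and 1.4e-05 for the respiratory chain. None was called with an estimated correlation, which does not decide for the reason given. Camera's adjusted p was then 0.776 for G1/S and 0.782 for G2/M, mitochondrial transcripts and the proteasome. It was 0.815 for the respiratory chain and 0.84 for ribosomal proteins. Hypoxia genes (3 rose of 22, 4 adjusted over the list alone, DESeq2 0; adjusted p = 0.0201) and cholesterol synthesis genes (2 fell of 23, 2 adjusted over the list alone, DESeq2 0; 0.0495) were also called, with adjusted p = 0.782 with an estimated correlation for both.

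These p53-M133T results stood beside trends with exon length and GC content. The ATO ratio correlated with exon length across genes at a Spearman coefficient of 0.317 in p53-M133T cells, against 0.028 in p53-R273H cells and 0.121 in vector cells. With GC content it was -0.366, -0.376 and -0.349 in the same order. Between p53-M133T and vector cells that had both received ATO it was 0.028 with length and 0.321 with GC content, and between p53-M133T and p53-R273H cells with ATO it was -0.052 and 0.423. The median exon length was 10397 bp for the 783 genes that rose outside the p53 core targets, against 5007 bp for all tested genes. With a length and GC correction 278 genes rose and 364 fell, and in the 3 treated libraries alone 95 rose and 179 fell. DESeq2 gave 158 and 3. The p53 core targets counted 28 risen with the correction and 32 in the treated libraries alone, with 0 falling in either. In the treated libraries alone 6 G1/S genes fell, 4 G2/M genes fell, and 0 mitochondrial transcripts, 0 proteasome subunits, 0 ribosomal proteins and 0 respiratory chain genes fell. With the correction 3 G2/M genes, 2 ribosomal proteins and 5 respiratory chain genes fell, and with a mean of at least 10 CPM 10 G2/M genes and 6 respiratory chain genes fell. Of other groups that rose across the lines, few or no members were called in this test: 0 of 5 metallothionein and zinc export genes and 0 of 23 ATF4 genes were called by edgeR (0 and 1 at an unadjusted p under 0.05) and by DESeq2 (0 and 0), and 1 of 28 NRF2 genes and 1 of 16 autophagy and lysosome genes were called. Of 18 heat shock genes edgeR called 0 (3 falling at an unadjusted p under 0.05) and DESeq2 0. HMOX1 differed by -0.09 (adjusted p = 0.7 by edgeR). Median, mean and camera differed in sign for the NRF2, NF-kB, mesenchymal, intestinal epithelial and WNT lists. This test had 1 residual degree of freedom and takes the vector and p53-R273H lines as replicates of each other. BLOC1S5-TXNDC5, ZACN and SLX1B also passed, with 0, 5 and 37 counts in p53-M133T cells with ATO against 260, 495 and 796 without, and are uncertain.

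**Figure D3:**
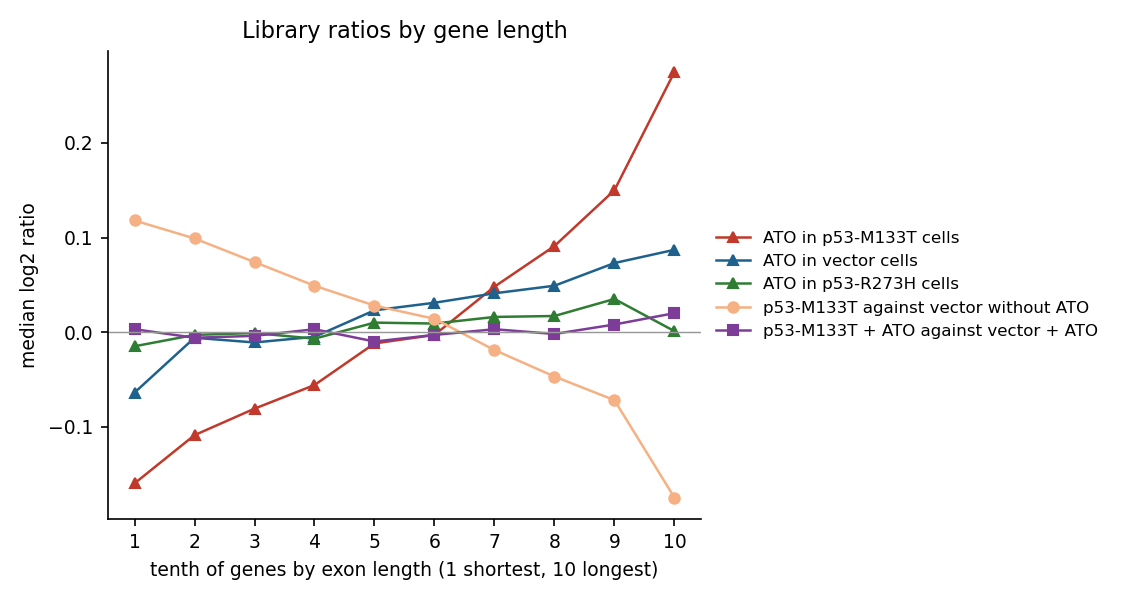
Median log2 ratio in 10 equal groups of genes ordered by exon length, for 5 comparisons, 1 line each. Across genes the Spearman correlation with length was 0.317 for ATO in p53-M133T cells and -0.431 for p53-M133T against vector without ATO.

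The comparison of p53-R273H cells with and without ATO asked the same of this variant. CDKN1A was higher by 1.21-fold (1.15 to 1.28), MDM2 by 1.23-fold (1.18 to 1.27) and GDF15 by 3.59-fold (3.45 to 3.74), and SESN1 had a ratio of 1.03 (0.856 to 1.24). The p53 core target median was 0.04 (percentile 74.31) and did not stand apart. Hypoxia genes (-0.15), ribosomal proteins (0.16) and the stress-shared p53 targets (0.48) were among the lists that did. In all, 75 genes were at least 2-fold higher and 99 at least 2-fold lower, and 66 and 115 when scaled by column totals. The test of p53-R273H cells takes its spread from the difference between the vector and p53-M133T effects. An effect particular to p53-M133T cells widens it, so its calls cannot be set beside those of p53-M133T. Relative to the other lines 21 genes rose and 10 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the genes that rose, 12 were mitochondrially encoded transcripts, of 13 tested (13 adjusted over the list alone; DESeq2 4; without genes that share exons 8 of 8), with MT-ATP8 at a log2 difference of 1.17 (SE 0.15; adjusted p = 3.1e-05) and MT-ND1 at 0.93 (1.4e-04). Their share of counts was 3.77% without ATO and 3.64% with ATO, against 3.69% and 2.3% in vector cells. These transcripts moved together, and the preset correlation takes them as almost independent, so the size of camera's p-value does not measure the evidence. Camera called them (adjusted p = 1.2e-61), with adjusted p = 0.968 with an estimated correlation. Of 78 p53 core targets 0 rose and 0 fell by edgeR (1 and 12 at an unadjusted p under 0.05; 0 and 4 adjusted over the list alone) and 0 and 0 by DESeq2, while 5 fell with no filter and 3 with the length and GC correction. Camera placed the list lower (adjusted p = 8.17e-08), with adjusted p = 0.968 with an estimated correlation. This test subtracts the mean of the vector and p53-M133T lines, and the core target median was 0.04 in p53-R273H cells, 0.02 in vector cells and 0.37 in p53-M133T cells, so it does not place p53-R273H cells below vector cells. Camera called 10 lists in this test. The other 8 were higher for ATF4 (adjusted p = 1.12e-04), G1/S (2.19e-04), ribosomal proteins (3.85e-04), the respiratory chain (0.00152) and the proteasome (0.0177), and lower for hypoxia (0.00152), p53 DNA repair (0.00234) and p53 apoptosis (0.0128), with adjusted p = 0.968 with an estimated correlation for each. With the length and GC correction 26 genes rose and 25 fell, without genes that share exons 11 and 11, with no filter on low counts 35 and 66, with a mean of at least 10 CPM 16 and 22, and by DESeq2 4 and 1. Median, mean and camera differed in sign for the ER unfolded protein response, cholesterol synthesis, mesenchymal, intestinal epithelial and ribosome biogenesis lists. Against vector without ATO, p53-R273H cells had medians of -0.203 for ATF4 and -0.145 for ribosomal proteins. They had -0.092 for the respiratory chain, -0.032 for the proteasome and 0.003 for G1/S. A low untreated library raises the ATO ratio, and its share in the higher calls was not tested. The p53 apoptosis (-0.168) and DNA repair (-0.101) lists were also low without ATO, yet camera placed them lower.

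The comparison of vector cells with and without ATO gave the response without introduced p53. GDF15 was higher by 3.13-fold (3.03 to 3.24), MDM2 by 1.48-fold (1.43 to 1.53) and CDKN1A by 1.38-fold (1.3 to 1.46), while BBC3 had a ratio of 0.889 (0.789 to 1.0). The p53 core target median was 0.02 (percentile 49.52) and did not stand apart. The stress-shared p53 targets (0.21), WNT targets (-0.21), histones (-0.5), the respiratory chain (-0.08) and erythroid and endothelial markers (-1.63) were among the lists that did. Over 4 members, the erythroid and endothelial medians against vector without ATO were -1.836 for p53-M133T, -1.957 for p53-R273H and 0.154 for wild-type p53. Their fall in vector cells thus starts from a level that the untreated p53-M133T and p53-R273H libraries lacked, and cannot be assigned to ATO. The metallothionein median was 2.83 in vector cells, 2.78 in p53-M133T cells and 2.70 in p53-R273H cells. In vector cells 85 genes were at least 2-fold higher and 125 at least 2-fold lower, and 73 and 179 when scaled by column totals. The test of vector cells takes its spread from the difference between the p53-M133T and p53-R273H effects. An effect particular to p53-M133T cells widens that spread. The common coefficient of variation was 0.091 here and 0.042 in the test of p53-M133T, so their numbers of calls cannot be set side by side. Relative to the other lines edgeR called 0 genes (178 at an unadjusted p under 0.05) and DESeq2 called 2, both falling, while 2 rose and 3 fell with no filter on low counts and 6 fell in the treated libraries alone. Camera placed the p53 core targets lower (adjusted p = 8.63e-09; adjusted p = 0.928 with an estimated correlation), in a test that uses the same 6 libraries as that of p53-M133T and subtracts that line. Camera called 13 lists in this test. Of the others, erythroid and endothelial markers (adjusted p = 4.92e-09), histones (4.94e-08), stress-shared p53 targets (3.19e-06), p53 apoptosis (2.46e-04), ATF4 (0.0071), p53 DNA repair (0.0288), mitochondrially encoded transcripts (0.0327) and interferon-stimulated genes (0.0437) were lower. G1/S (7.89e-06), heat shock (3.62e-04), G2/M (0.0242) and NF-kB genes (0.0288) were higher, and each of the 12 had adjusted p = 0.928 with an estimated correlation. Median, mean and camera differed in sign for the NRF2, ER unfolded protein response, hypoxia, mesenchymal, WNT and PML lists.

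Whether ATO moved cells toward the wild-type p53 profile was asked with the genes that differed between wild-type p53 and vector cells. Across all genes, the log2 ratio of wild-type p53 to vector correlated with the ATO ratio at a Pearson coefficient of 0.038 in p53-M133T cells and -0.114 in p53-R273H cells. Across the p53 core targets it was 0.474 (Spearman 0.352) in p53-M133T cells and 0.081 (Spearman 0.098) in p53-R273H cells, and genes are not independent replicates. The 364 genes higher in wild-type p53 cells had a median ATO log2 ratio of -0.065 (percentile 9.96) in p53-M133T cells and -0.21 (percentile 0) in p53-R273H cells. The 248 lower genes had a median of -0.14 (percentile 0) in p53-M133T cells and 0.02 (percentile 74.32) in p53-R273H cells. Both lists were made from these libraries, and the wild-type library's batch and genotype cannot be told apart.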

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

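All tests of explanations given here, the length and GC correction and the comparison of treated libraries alone were chosen after the results were seen. In the comparison of treated libraries alone the line tested has 1 library, which is assumed to vary like the libraries of the other lines.

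The difference between lines in the ATO effect was itself tested, by edgeR, and singled out these results. In p53-M133T cells 816 genes rose and 340 fell relative to the vector and p53-R273H lines. Among the members that rose were 33 p53 core targets, 8 p53 targets shared with stress pathways, 8 p53 apoptosis targets and 5 p53 DNA repair targets. Among those that fell were 13 G1/S genes, 6 G2/M genes, 4 proteasome subunits, 4 ribosomal proteins and 13 mitochondrially encoded transcripts. For these groups, in the same order, DESeq2 called 0, 0, 0, 1 and 0 falling, and 6, 4, 0, 0 and 0 fell among the treated libraries alone. Mitochondrially encoded transcripts took 4.59% of the counts of the untreated p53-M133T library, the highest share of the 7 libraries. The log2 differences were 1.7 for CDKN1A, 1.64 for MDM2, 0.67 for BBC3, 0.49 for BAX, 0.91 for FAS, 0.74 for GDF15, 1.49 for SESN1, 1.2 for ZMAT3 and 0.71 for TIGAR. Of the genes named by rule 54 passed in p53-M133T cells, but the rule took part of its genes from those past the threshold, so this count is no support. In p53-R273H cells 21 genes rose and 10 fell relative to the vector and p53-M133T lines, with 12 mitochondrially encoded transcripts among those that rose. Within p53-R273H cells these transcripts kept their level with ATO, at a median log2 ratio of 0.01, against -0.91 in p53-M133T cells and -0.62 in vector cells. Of the genes named by rule 13 passed, with the same limit.

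The rises in p53-M133T cells with ATO were weighed against a trend with gene length and GC content and against an untreated p53-M133T library that stood apart, and the p53 core targets and the other genes came out differently. Of the 33 core targets that rose, 27 rose also with the length and GC correction and 24 were also higher among the treated libraries alone, with a median log2 difference of 0.8 (median SE 0.119), then 0.675 (0.118) and 0.67 (0.091), which argues against either as the whole cause, for the second as far as the spread between the other lines holds. Of the other 783 genes, 248 rose with the correction and 42 were also higher among the treated libraries alone, and their median went from 0.447 (0.101) to 0.27 (0.105) and 0.08 (0.076), so calls ended because the differences shrank, and both remain candidate explanations. For the core targets, activity of p53 like that of the wild-type protein may account for the rise: their ATO ratio correlated at 0.474 with the wild-type to vector ratio, against 0.081 in p53-R273H cells, under a bound set with these values known. Across all genes that correlation was 0.038. The 364 genes higher with wild-type p53 had a median ATO log2 ratio of -0.065 (percentile 9.96), against -0.209 (percentile 0) in p53-R273H cells. The 248 genes lower with wild-type p53 had one of -0.138 (percentile 0), against 0.021 (percentile 74.32) in p53-R273H cells. Single libraries leave differences between cultures open.

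The mitochondrially encoded transcripts that rose in p53-R273H cells relative to the other lines were weighed against 3 technical explanations. With the length and GC correction 11 transcripts rose, and 13 were higher in p53-R273H cells among the treated libraries alone, with the spread taken from the other lines, which argues against a length trend and against the untreated libraries as the whole cause as far as that spread holds. A capture of mitochondrial RNA that differed in 1 library could account for it and cannot be told apart from an effect of the line, since p53-R273H cells with ATO have 1 library.

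The number of genes changed by ATO across the lines was compared with other splits of the 6 libraries into 3 and 3. The real split gave 5859 genes, 1 of 10 splits gave as many, and the highest other split gave 0, also among those that part as many pairs. With 10 splits a share under 0.05 cannot be reached. In the other splits the ATO effect counts as spread and lowers their calls, so 5859 against 0 does not measure chance.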

How the results depend on the processing

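The length and GC correction, the removal of genes sharing exons and the tests on treated libraries alone were chosen after the data were examined, and the cause of the shifts below was not tested unless stated. Of 240 camera results 187 were the same, 4 gained a call and 49 lost it. With the estimated correlation 45 calls were lost and 0 lists stayed called. Of 886 list medians 842 were the same, 23 came to stand apart and 21 ceased to. Results called in neither setting count as the same, and as kept for the named genes in the tests. Of 1691 values of named genes in the tests 1569 kept their call, 27 gained it, 90 lost it and 5 reversed, and of 816 in pairs of libraries 786 stayed and 30 moved. Of 178 counts and correlations 100 stayed within 1.5 times or their interval. The pseudocount was not varied in the tests, which use counts. A count of 0 allows between 0.076 and 0.116 CPM, and differences below that were not detectable at this depth.

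Across the lines, 1511 genes rose and 1403 fell without the vector pair, against 3585 and 3254 without the p53-M133T pair and 2727 and 2445 without the p53-R273H pair. With no replicate block 2620 rose and 2656 fell. With the length and GC correction 3347 rose and 2427 fell, among them 2406 and 1953 of the genes called without it.

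Relative to the other lines, DESeq2 gave 158 risen and 3 fallen genes in p53-M133T cells (no adjusted p for 7044), 4 and 1 in p53-R273H cells, and 2 fallen in vector cells. With the length and GC correction 278 rose in p53-M133T cells, 25 fell in p53-R273H cells, and 1 rose and 2 fell in vector cells. Among treated libraries alone 95 rose and 179 fell in p53-M133T cells and 6 fell in vector cells. With no filter 35 rose and 66 fell in p53-R273H cells, and 2 rose and 3 fell in vector cells. With a mean of at least 10 CPM 22 fell in p53-R273H cells, and without genes sharing exons 11 rose. Among treated libraries alone the log2 difference in p53-M133T cells reversed to -0.04 for MKI67, -0.007 for CENPF, 0.016 for PSMB3, 0.017 for RPS14 and 0.008 for RPL27.

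The counts of genes in pairs of libraries moved by over 1.5 times with both size rules, as a stricter or looser rule must, and with a pseudocount of 5, which shrinks ratios. They are given as higher and lower, for ATO in p53-M133T, p53-R273H and vector cells, then wild-type p53, p53-M133T and p53-R273H against vector. With the 1.5-fold rule they were 862 and 751, 405 and 645, 410 and 713, 1123 and 1025, 28 and 120, 36 and 64. With the 3-fold rule they were 33 and 11, 17 and 10, 22 and 14, 108 and 35, 4 and 3, 2 and 4. With a pseudocount of 5 they were 83 and 36, 39 and 31, 46 and 31, 186 and 128, 2 and 0, 1 and 0. With a pseudocount of 0.1 they were 271 and 322 for ATO in p53-M133T cells, 135 and 302 in p53-R273H cells and 126 and 358 in vector cells. They were 528 and 408 for wild-type p53, 28 and 81 for p53-M133T and 34 and 61 for p53-R273H against vector, of which 126 and 528 stayed within 1.5 times. With a floor of 10 CPM, 80 were lower with ATO in p53-M133T cells and 82 in vector cells, and the counts against vector were 2 and 6 for p53-M133T and 2 and 1 for p53-R273H. Without genes sharing exons 3 were higher for p53-M133T, and 2 were higher and 7 lower for p53-R273H, against vector.

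The median ATO log2 ratio in p53-M133T cells of the genes higher with wild-type p53 stood apart against unmatched random lists (-0.065) and with a floor of 10 CPM (-0.09). That of the lower genes in p53-R273H cells stood apart as a mean (0.05). The correlation across all genes was 0.071 (Spearman) and 0.062 (floor of 10 CPM) in p53-M133T cells and -0.083 (Spearman) in p53-R273H cells. Camera's adjusted p for p53 core targets with an estimated correlation was 0.7762 in p53-M133T, 0.9683 in p53-R273H and 0.9276 in vector cells.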

Other observations

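All tests of explanations in this part were chosen after the results were seen.

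Among the 8 genes at or above 10 CPM that fell furthest with ATO across the lines were DBP, a transcription factor with a daily rhythm, and PER2 and PER1, which encode repressors of the circadian clock. DBP fell to 0.201-fold (edgeR adjusted p = 2.9e-06), PER2 to 0.283-fold (4.2e-05) and PER1 to 0.322-fold (8.3e-06), and PER1 shares exons with another gene. DBP had ratios of 0.219 (0.19 to 0.253) in vector cells, 0.202 (0.175 to 0.232) in p53-M133T cells and 0.184 (0.157 to 0.215) in p53-R273H cells. No list of clock genes was fixed or tested, so nothing is said of such genes as a group.

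Some genes had 0 or few counts in some libraries and many in others. CXCR5 had 0 counts with wild-type p53, 535 and 372 in vector cells without and with ATO, 847 and 504 in p53-M133T cells and 230 and 0 in p53-R273H cells. ZACN had 419 counts with wild-type p53, and in the same order of lines 143 and 79, 495 and 5, and 439 and 350. AC007192.4, which shares exons with another gene, had 2313 counts with wild-type p53 and between 0 and 23 in the other libraries. Of 67 genes at least 4-fold different between wild-type p53 and vector cells, 16 share exons on the same strand, against 1339 of all 12661 genes. HBB had 217 counts with wild-type p53, 156 and 5 in vector cells without and with ATO, and between 0 and 2 in the p53-M133T and p53-R273H libraries.

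The higher interferon-stimulated and hypoxia genes of the wild-type p53 library were weighed as a further pattern. Of the 34 members at least 2-fold higher, of 42 in both lists, 4 share exons with another gene, which argues against reads divided between such genes as the cause. The interferon-stimulated list had a median log2 ratio of 0.013 (quartiles -0.378 and 0.12) with ATO in p53-M133T cells. It was -0.12 with ATO in p53-R273H cells and -0.141 in vector cells. The p53 core targets had a median of 0.369 with ATO in p53-M133T cells and 0.302 with wild-type p53. The core targets thus rose in p53-M133T cells without a rise of this list. Treatment with ATO and wild-type p53 without ATO differ in more than p53 activity, so this does not decide whether wild-type p53 raised the list. A library batch could account for the pattern and cannot be told apart from the genotype, since 1 library carries that name prefix. The level of oxygen or cell density at harvest was not given in the sources used here.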
